A study of Mus musculus with 217 samples.

How the data were processed

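The study measured messenger RNA of mouse oocytes and of granulosa cells, the somatic cells that surround and nourish the oocyte, in wild-type and Tet2 knockout mice of 3 ages with or without resveratrol. Per the labels' protocols, mice were primed with pregnant mare serum gonadotropin, granulosa cells were released by puncturing visible follicles, and oocytes were taken out of the granulosa pools with a 40 µm strainer. Metaphase II oocytes were collected after hCG injection and freed of cumulus cells with hyaluronidase. Libraries were made with Smart-seq2 and sequenced as paired reads of 150 bp. The labels give the granulosa cells per pool as 500 in one place and 50 in another, so the number is unsettled.

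The authors deposited 3 tables of whole-number read counts per gene, not normalized, each with 53619 genes. The submitters' processing notes name HISAT2 2.1.0, featureCounts, DESeq2 and the mm10 genome, with no roles, and whether counting used strand is not given in the sources used here. Reads of overlapping, antisense or near-identical genes can therefore not be told apart. The tables hold gene symbols only, of which 28471 matched the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names. Positions come from that annotation, and genes named after genomic clones (beginning RP23 or RP24) have none here. None of the 13 mitochondrially encoded transcripts had a symbol in the tables. No sample column was left unused, and no pair of libraries held identical values.

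Groups were taken from the sample titles. The 18 young wild-type oocytes carry a genotype tag of knockout that contradicts their title, and the title was followed. A C57BL6 oocyte whose title and treatment tag disagree was left out of its group and entered 1 alternative only. No animal is named for any oocyte or granulosa library, so p-values measure only the spread between these samples, which may be technical.

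Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with TMM factors, a filter on low counts (filterByExpr, minimum count 10) and Benjamini-Hochberg adjustment at 0.05. "Adjusted p" of a gene means this value throughout. For granulosa cells 1 model held a mean for each of the 6 groups of 3 libraries, with 12 residual degrees of freedom and 17558 genes tested, and the biological coefficient of variation was 0.306. Interactions were contrasts of the same model. Single oocytes are not replicates of a mouse, so the counts of each of the 10 oocyte groups were summed. The 10 sums entered an additive model of age, genotype and treatment with 5 residual degrees of freedom, or 4 with the treatment by genotype interaction, and 20806 genes were tested. With 1 sum per group, the spread in this model is the departure of the sums from additivity. An effect of knockout or resveratrol that is particular to some ages therefore counts as spread, as does one particular to a genotype without the interaction. A filter on oocytes under 500000 counts or 5000 genes removed 0 oocytes. The C57BL6 table gives 1 sum per group and no test. Its log2 ratios of sums, with 0.5 counts added, carry exact conditional Poisson 95% intervals, and a list's median is placed among 10000 random lists matched on mean expression.

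Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within each comparison. Of the 310 list tests in all comparisons, 79 passed (49 higher, 30 lower), and 3 passed with an estimated correlation. List adjusted p-values are at the preset correlation unless an estimated correlation is named. A fold against a group without counts uses a floor of 3 counts over the group and is written as a lower bound. With 1 to 3 counts a ratio with its 95% counting interval is given in place of the fitted fold. Single-library shares carry 95% Wilson intervals. Intervals and floors cover counting error only.

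Apart from the additions named below, the groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule Tet1, Tet2 and Tet3 are always reported. It then takes the 6 largest rises and 6 largest falls past the threshold, at 10 CPM or more in the higher group. The granulosa libraries of the groups must not overlap, and for oocytes the direction must hold in every stratum. From each list it takes up to 4 passing members with the lowest p, or up to 2 not passing, to at most 30 genes per comparison. An interaction contributes the 4 genes with the lowest p, and a comparison without calls the 3 with the lowest p. Numbered gene models and numbered pseudogenes are not named. In the C57BL6 table the 4 highest and 4 lowest ratios at 50 CPM or more are taken. Other genes named are said to be chosen after their values were seen, and some genes the rule takes are not reported here. The means beside granulosa folds are TMM-scaled CPM (counts scaled to a common library total) with SD over 3 libraries, and those beside oocyte folds are over group sums.

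The test was run on simulated counts with known changes, 100 genes at each size. At 4-fold it recovered 76% for the age effect in wild-type granulosa cells, 91% for resveratrol in old wild-type cells, 97% for knockout in oocytes and 96% for resveratrol in oocytes. At 2-fold it recovered 20%, 43%, 51% and 38%. For knockout in young granulosa cells and for old against young oocytes it recovered 10% at 2-fold. False calls numbered from 3 (knockout in young granulosa cells) to 14 (resveratrol in old wild-type cells). The changed genes were drawn from those with higher counts only, so recovery among genes of low counts was not measured. Alternatives tried were RLE size factors, DESeq2 1.42.0, limma-trend, no filter or a stricter filter, fewer groups in the model, a replicate block, a block of strata, each replicate or group left out, and equal weights. Added after the data were seen were runs without the shallow granulosa libraries or with only the shallow young ones, thinning to one depth, sums per number in the oocyte headers, and use of the unassigned C57BL6 library. The test of genes near Tet2 and some tests of flagged results were added then too. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, intervals and figures.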

Results

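Smart-seq2, which amplifies full-length cDNA of polyadenylated RNA from single cells or small pools, gave 217 mouse libraries. Of these, 171 were single metaphase II oocytes in 10 groups, 18 were pools of granulosa cells in 6 groups of 3, and 28 were single oocytes of the C57BL6 strain. Mice were 2 (young), 6 (middle-aged) or 10 (old) months old and wild type or knockout for Tet2, which encodes an enzyme that oxidises 5-methylcytosine in DNA. Middle-aged and old mice drank water with resveratrol, a plant polyphenol, at 30 mg per L, or with its solvent DMSO as control. Wild-type oocytes numbered 18 young, 20 middle-aged control, 14 middle-aged resveratrol, 20 old control and 14 old resveratrol. Knockout oocytes numbered 15, 20, 20, 15 and 15 in the same order. The series title names the reprogramming of the aging ovary by resveratrol as its subject.

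Oocyte libraries held 3386039 to 8775154 counts and C57BL6 libraries 3470831 to 11358927. Granulosa libraries differed far more in depth. The 3 young wild-type pools held 639907, 470647 and 500603 counts and young knockout-labelled replicates 1 and 3 held 749172 and 722075, while young knockout-labelled replicate 2 held 11595710. The 12 old pools held 5995491 to 20537935 counts. Age and depth therefore coincided in granulosa cells except in that 1 young library. The first principal component carried 32.6% of the variance and set the 5 shallow libraries apart. Young knockout-labelled replicate 2, at 24.6 on this component, lay within the range of the old wild-type controls, 21.7 to 30.1.

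**Figure D1:**
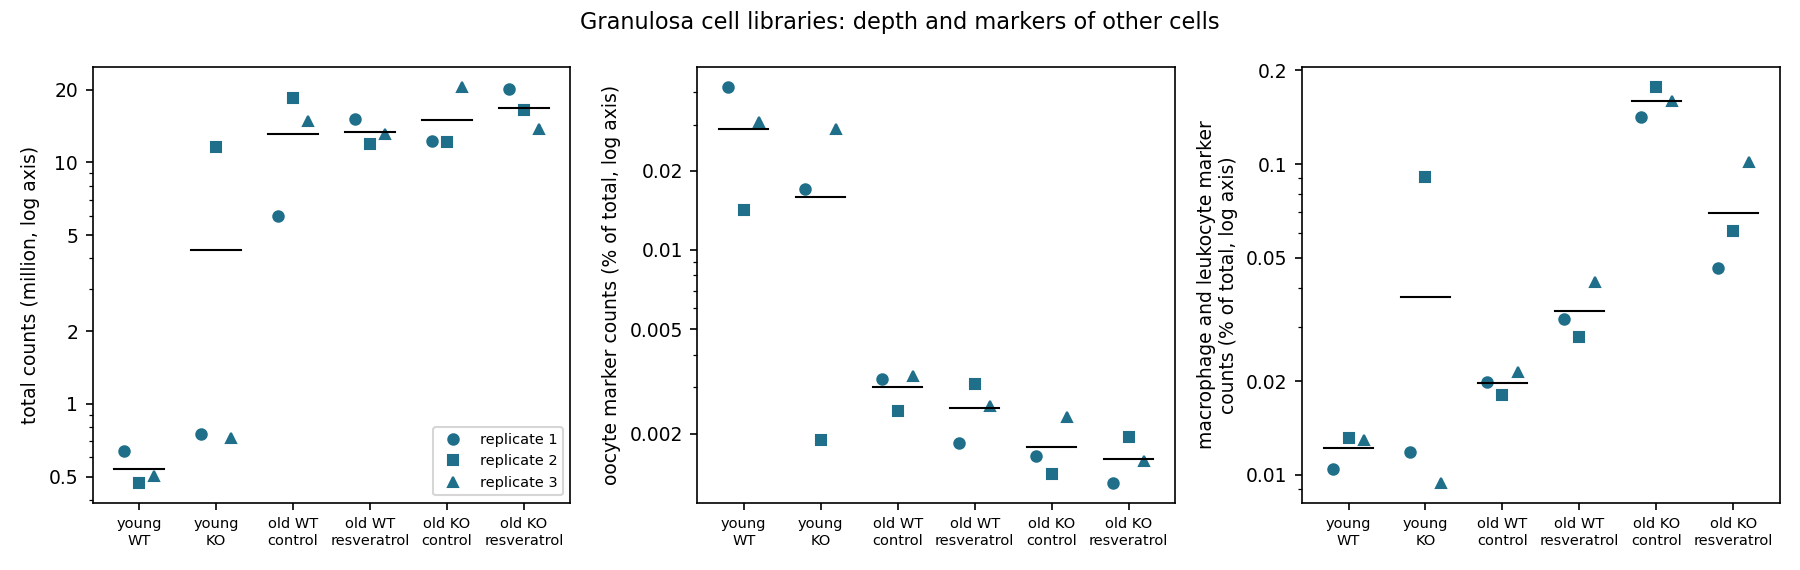
Total counts (in units of 1000000), the percent of counts from 14 oocyte markers and the percent from 17 macrophage and leukocyte markers in each granulosa library, on log axes; points are the 3 libraries of a group and lines their means. Oocyte markers are highest in the 5 shallow young libraries, and macrophage markers in old knockout-labelled controls (0.142 to 0.177%).

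Tet2 lies on chromosome 3 from 133463679 to 133545139 (GRCm38, minus strand). In oocytes it was lower in knockout than in wild-type group sums, 1.13 ± 0.179 against 2.89 ± 0.375 CPM (SD, n = 5 sums each; log2 −1.36, SE 0.19, adjusted p = 0.036), in 5 of 5 strata. Leaving out 1 sum at a time gave log2 −1.46 to −1.26 with adjusted p-values of 0.0441 to 0.129 in edgeR. The call held without young wild-type or young knockout oocytes and was lost without each of the other 8 sums, and with strata as a block (adjusted p = 0.0848). The sums were 3.1 (young), 3.19 and 2.36 (middle-aged control and resveratrol), 2.62 and 3.17 (old control and resveratrol) in wild type, and 1.02, 1.22, 1.05, 1.4 and 0.961 in knockout. The young wild-type oocytes with the contradictory tag, at a median of 2.83 CPM, fell among the wild-type medians of 1.75 to 3.22 and above the knockout medians of 0.69 to 1.38. In granulosa cells Tet2 was not lower in the pools labelled knockout. It measured 8.09 ± 3.82 (young wild type) and 11.8 ± 4.18 CPM (young knockout label; log2 0.55, SE 0.48, adjusted p = 0.697). Old controls held 11.6 ± 1.63 (wild type) and 15.7 ± 5.14 CPM (knockout label; log2 0.43, SE 0.29, adjusted p = 0.479), and old resveratrol pools 14.6 ± 2.01 and 14.9 ± 4.06. The deleted part of the gene is not given in the sources used here, so counts over the whole gene check the genotype only in part. These pools are called labelled knockout throughout. Tet3 was abundant in oocytes, at 702 ± 37 CPM in knockout and 708 ± 91.9 in wild type, and Tet1 and Tet3 passed in no comparison.

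**Figure D2:**
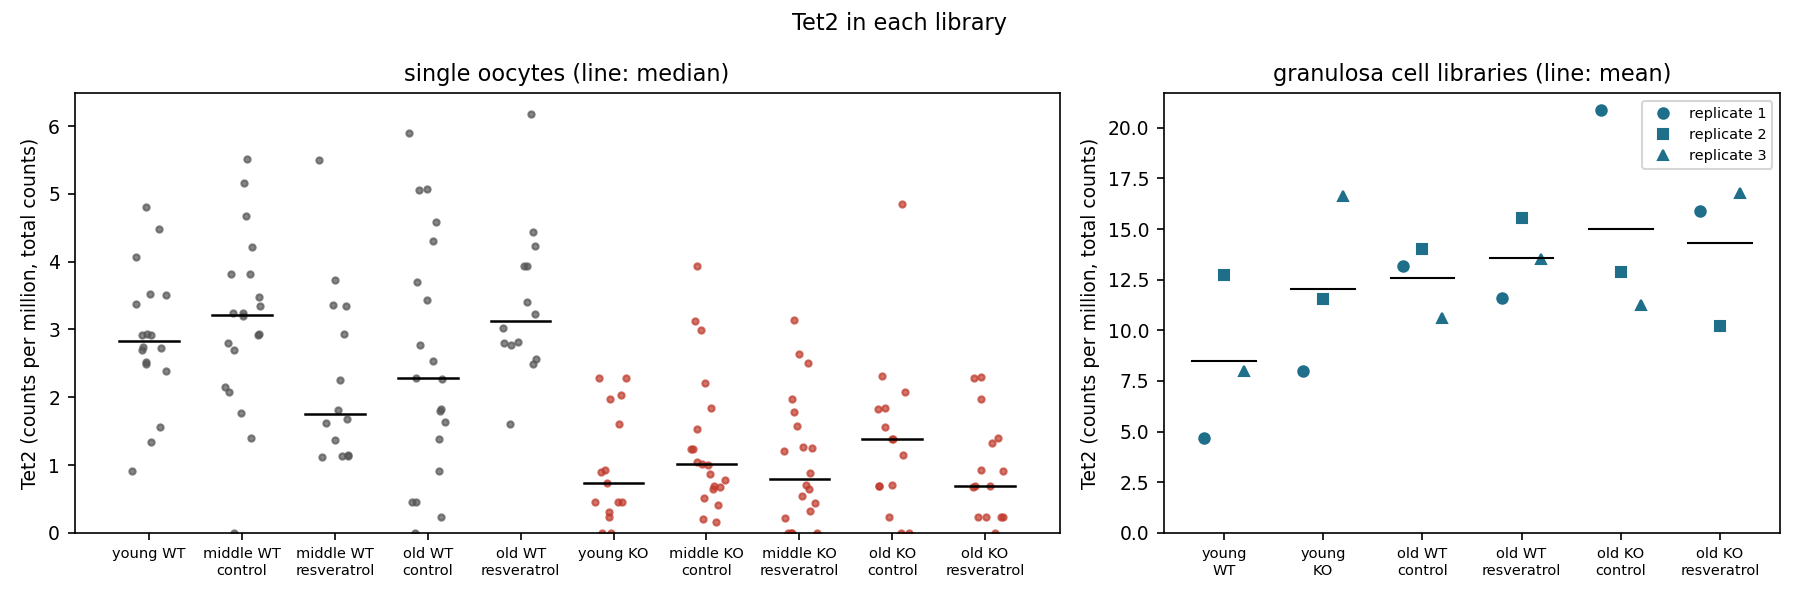
Tet2 in CPM of total counts for each oocyte by group and for each granulosa library. Lines are the group median for oocytes and the group mean for granulosa libraries. Oocytes are grey for wild type and red for knockout. Granulosa libraries share a colour, with a marker shape for each replicate. Oocyte medians are 1.75 to 3.22 in wild type and 0.69 to 1.38 in knockout, whereas granulosa pools of both labels overlap.

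The first granulosa comparison set old against young wild-type cells without resveratrol. Vnn1, which encodes the pantetheinase vanin 1, rose from 8.47 ± 7.35 to 1650 ± 34.1 CPM (SD, n = 3 each; log2 7.54, SE 0.92, adjusted p = 7.91e-05). Its age effect was more negative under the knockout label (difference in log2 −6.92, adjusted p = 0.00378), so this rise describes wild-type pools only. Young pools labelled knockout already held more Vnn1 than young wild-type pools (log2 5.48, adjusted p = 0.00548). The metallothionein gene Mt2 rose from 124 ± 6.62 to 378 ± 52.5 CPM (log2 1.61) and Cdkn1b, the cyclin-dependent kinase inhibitor p27, from 15.5 ± 6.72 to 108 ± 26.2 (log2 2.77). Transcripts known from oocytes fell, among them those of the secreted growth factors Gdf9 (81.7 ± 38.9 to 1.77 ± 0.947 CPM) and Bmp15 (30.9 ± 18.1 to 0.207 ± 0.359). Oas1d was at least 463-fold lower, and Tcl1 was lower by a ratio of 748 (counting interval 248 to 3694).

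By list in this comparison, 6 of 11 measured oocyte markers fell (8 adjusted over the list alone), with an adjusted p of 2.52e-11 (adjusted p = 0.0721 with an estimated correlation). Oocyte markers took 0.0417% (95% Wilson interval 0.0370 to 0.0470), 0.0142% (0.0112 to 0.0181) and 0.0306% (0.0261 to 0.0358) of counts in young replicates 1, 2 and 3, and 0.00130 to 0.00331% in the 12 old pools. Of 32 cell cycle genes 1 fell, Aurkb (log2 −1.49, SE 0.35), and 5 adjusted over the list alone (adjusted p = 2.52e-11, and adjusted p = 0.0721 with an estimated correlation). Of 45 cytosolic ribosomal protein genes 2 rose, among them Rpl3 (log2 0.78), or 29 adjusted over the list alone (adjusted p = 2.79e-14, and adjusted p = 0.191 with an estimated correlation). No nuclear-encoded oxidative phosphorylation gene of 56 passed, 9 rose adjusted over the list alone, and the list was higher at an adjusted p of 2.33e-09 (adjusted p = 0.291 with an estimated correlation). In the luteinization and steroidogenesis list 2 of 18 rose, Mt2 and Cdkn1b, or 8 adjusted over the list alone (adjusted p = 1.7e-05, and adjusted p = 0.0721 with an estimated correlation). In the list of granulosa identity and response to follicle-stimulating hormone 1 of 20 fell, Slc18a2 (log2 −1.59), or 3 adjusted over the list alone (adjusted p = 0.00251, and adjusted p = 0.0721 with an estimated correlation). Of 22 unfolded protein response genes 2 rose, Ddit3 (log2 1.21) and Pdia4 (1.7), or 3 adjusted over the list alone. Of 20 heat shock genes 1 rose, Hspe1 (106 ± 21 to 229 ± 10.4 CPM), and 1 fell, Hspa4l (−1.14), or 3 and 2 adjusted over the list alone. Neither list passed as a whole (adjusted p = 0.228 for each). Macrophage and leukocyte markers passed in 0 of 17, and the list was higher at an adjusted p of 0.0367 (adjusted p = 0.438 with an estimated correlation).

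Altogether, 268 genes passed between old and young wild-type pools, 148 higher and 120 lower in old. Falls outnumbered rises with RLE size factors (82 higher and 137 lower), which moved the median log2 change of all genes by −0.108. They did so by DESeq2 (197 and 326) and with only the groups compared in the model (397 and 539) too. The count was 66, 111 and 60 without young replicates 1, 2 and 3, and 91, 75 and 120 without old control replicates 1, 2 and 3. All 3 young pools were shallow, and at one depth for all libraries 173 genes passed.

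In pools labelled knockout, old against young control cells held more transcripts of ribosomal protein and nuclear-encoded oxidative phosphorylation genes. Of 45 cytosolic ribosomal protein genes 35 rose (40 adjusted over the list alone), among them Rpl37 from 260 ± 49.6 to 651 ± 57.8 CPM (SD, n = 3 each; log2 1.34, SE 0.20, adjusted p = 0.000712). Of 56 oxidative phosphorylation genes 28 rose (35 adjusted over the list alone), among them the ATP synthase subunit Atp5k (log2 1.51, SE 0.22) and the cytochrome oxidase subunit Cox6c (log2 1.18, SE 0.19). These lists had adjusted p-values of 9.33e-29 and 3.46e-20 (adjusted p = 0.0684 and adjusted p = 0.0716 with an estimated correlation). Leukocyte transcripts rose too: 7 of 17 macrophage and leukocyte markers passed, 14 adjusted over the list alone. Among them were the antigen presentation genes H2-Aa (log2 4.98) and Cd74 (log2 4.72, SE 0.71), at 81.3 ± 19.5 and 165 ± 40.5 CPM in old pools. That list held with an estimated correlation (adjusted p = 2.64e-17, and 0.00773 with an estimated correlation). Its markers took 0.159 ± 0.0176% of counts in old pools, against 0.0119% (95% Wilson interval 0.00965 to 0.0146), 0.0911% (0.0893 to 0.0928) and 0.00942% (0.00743 to 0.0119) in young replicates 1, 2 and 3.

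The immunoglobulin light chain gene Igkv3-4 was at least 153-fold higher in old than in young pools labelled knockout, at 27.8 ± 43.6 CPM (1.01 to 78.1), and the ratio for Iglc2, another such gene, was 161 (counting interval 55 to 782). Without old control replicate 3, which held most counts of both, the first was at least 10.9-fold higher, no longer past the threshold (adjusted p = 0.0596 in edgeR), and the ratio for the second was 85.9. The call of Igkv3-4 was also lost without young replicate 2 or 3 (adjusted p = 0.0984 and 0.051 in edgeR). By DESeq2 it was 0.141, with only the groups compared 0.102, and without the 5 shallow libraries 0.0762. The call held without young replicate 1 or old control replicate 1 or 2, with RLE size factors, without a filter and with a replicate block. Both immunoglobulin genes belong to families of near-identical members, so their counts are uncertain. Falls included Mtfr2, a mitochondrial fission regulator (log2 −6.51, SE 0.73), Bcl2l10 (−4.0) and the apolipoprotein gene Apoc1 (−3.89). Pla2g4c was at least 27.5-fold lower, or 15.8-fold without young replicate 3. Oocyte markers fell in 7 of 11 (8 adjusted over the list alone; adjusted p = 3.07e-07, and adjusted p = 0.135 with an estimated correlation). They took 0.0171% (95% Wilson interval 0.0144 to 0.0203), 0.00189% (0.00165 to 0.00216) and 0.0289% (0.0253 to 0.0331) of counts in young replicates 1, 2 and 3. Cell cycle genes fell in 4 of 32, including Ccna2 (−0.72) and Bub1b (−1.29), or 14 adjusted over the list alone (adjusted p = 4.78e-09, and adjusted p = 0.0716 with an estimated correlation).

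In this comparison 908 genes passed, 719 higher and 189 lower in old pools labelled knockout, or 453 and 236 with RLE size factors. Without young replicate 2, the deep library, 1397 passed, and 412 passed without young replicate 3. The count fell to 343 and 376 without old control replicates 1 and 2, and at one depth it was 341.

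Old granulosa pools of both labels shared 59 of the genes higher with age and 47 of those lower, where independent lists of these sizes would share 6.06 and 1.29. The comparisons have no library in common, but all 3 young wild-type and 2 of 3 young knockout-labelled pools were shallow, with a larger share of oocyte markers than every old pool.

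Old wild-type granulosa cells held more transcripts of nuclear-encoded oxidative phosphorylation genes, ribosomal protein genes and macrophage markers with resveratrol than without. Of 56 oxidative phosphorylation genes 18 rose (47 adjusted over the list alone), such as Cox6b1 from 495 ± 34.4 to 893 ± 91 CPM (SD, n = 3 each; log2 0.85, SE 0.18, adjusted p = 0.0273) and Cox7c (log2 0.92). Of 45 cytosolic ribosomal protein genes 8 rose (37 adjusted over the list alone), such as Rplp2 (log2 0.84) and Rpl19 (log2 0.69). The median log2 change was 0.70 over the first list and 0.58 over the second. Their adjusted p-values were 1.4e-26 and 5.11e-21 (adjusted p = 0.159 and adjusted p = 0.244 with an estimated correlation). The peroxiredoxin gene Prdx5, 1 of 4 of 28 antioxidant genes that rose (9 adjusted over the list alone), went from 156 ± 22 to 320 ± 23 CPM (log2 1.04, SE 0.16, adjusted p = 0.00418). For the antioxidant list the adjusted p was 0.00246 (adjusted p = 0.261 with an estimated correlation).

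Among macrophage and leukocyte markers 6 of 17 rose with resveratrol in old wild-type pools (6 up and 1 down adjusted over the list alone), including Cd68 (log2 2.29) and the signalling adaptor Tyrobp (log2 3.85). The list had an adjusted p of 8.04e-05 (adjusted p = 0.261 with an estimated correlation), and the markers took 0.0337 ± 0.00717% of counts against 0.0198 ± 0.00169% in controls. Ctsk, which encodes cathepsin K, rose to 116 ± 135 CPM from 4.85 ± 1.27 (log2 4.61, SE 0.60), the complement gene C1qb to 18.6 ± 18 from 0.684 ± 0.681 (log2 4.52), and the matrix protease gene Mmp9 was at least 287-fold higher at 22.0 ± 22.2 CPM, or 117-fold without resveratrol replicate 1. The chemokine gene Ccl9 (log2 5.53) and Trim12a (log2 9.03, SE 1.85; 107 ± 91.7 against 0.273 ± 0.317 CPM) rose as well, the latter with counts made uncertain by a close paralog. The cell cycle genes Ube2c (log2 1.46) and Birc5 (1.15) rose, 2 of 32 in their list and 10 adjusted over the list alone (adjusted p = 3.63e-05, and adjusted p = 0.261 with an estimated correlation). In the cholesterol synthesis list 1 of 24 rose, Nsdhl (log2 0.99), or 4 adjusted over the list alone (adjusted p = 0.000139, and adjusted p = 0.514 with an estimated correlation). Falls included Socs3, a feedback inhibitor of cytokine signalling (log2 −2.41, SE 0.45), the lipoxygenase gene Alox15 (−2.55) and the myosin kinase gene Mylk (−2.79).

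Resveratrol in old wild-type pools gave 285 genes past the threshold, 205 higher and 80 lower, or 93 and 72 with RLE size factors and 260 and 282 without a filter on low counts. The count was 17, 39 and 35 without resveratrol replicates 1, 2 and 3, and 3, 4 and 80 without control replicates 1, 2 and 3. Without the 5 shallow young libraries in the model it was 960, and at one depth 8.

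In old pools labelled knockout, 5 genes differed with resveratrol, 2 higher and 3 lower (618 at an unadjusted p under 0.05, 16 past the threshold by DESeq2). The unplaced clone gene RP24-250M7.2 rose from 4.45 ± 1.00 to 27.2 ± 10.2 CPM (SD, n = 3 each; log2 2.6, SE 0.36, adjusted p = 0.00862). The lysozyme gene Lyz1, a phagocyte transcript, fell from 35.5 ± 12.4 to 1.72 ± 1.86 CPM (log2 −4.40, SE 0.69, adjusted p = 0.0193). RP24-388D8.2 fell (log2 −2.54), Igkv3-4 was lower by a ratio of 885 (counting interval 245 to 7317), from 27.8 ± 43.6 CPM. Without control replicate 3, at 78.1 CPM, the ratio was 63.2 and the call was lost (adjusted p = 0.211 in edgeR). It was lost too without each resveratrol replicate (adjusted p = 0.215 to 0.304 in edgeR), by DESeq2 (0.81) and with only the groups compared (0.134). Without the 5 shallow libraries it was 0.0583. The call held without control replicate 1 or 2, with RLE size factors, without a filter and with a replicate block. The clone gene RP24-156K1.1, chosen after its values were seen, rose (log2 3.90). Lyz1 has a close paralog, Lyz2, so its counts are uncertain. The inflammatory list had a median log2 change of −0.54 (adjusted p = 8.05e-06, and adjusted p = 0.0723 with an estimated correlation), with 0 of 22 members passing. Macrophage markers passed in 0 of 17, and 8 fell adjusted over the list alone (adjusted p = 2.03e-07, and adjusted p = 0.189 with an estimated correlation). Their share of counts was 0.0696 ± 0.0286% with resveratrol and 0.159 ± 0.0176% without. All 45 ribosomal protein genes lay above 0 at a median of 0.20 (adjusted p = 1e-07, and adjusted p = 0.434 with an estimated correlation), with 0 passing. The count was 0 without resveratrol replicate 2, 2 without replicate 3, 3 without control replicate 2 and 19 without control replicate 3.

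The resveratrol effect differed by genotype label in 28 genes, 26 of which were more negative under the knockout label and 2 more positive. The balance was less one-sided in other settings, with 50 more negative and 24 more positive by DESeq2, 150 and 102 without a filter on low counts, and 30 and 21 without control replicate 3 of the knockout label. They include genes of phagocytes. Cd68, a lysosomal protein of macrophages, measured 37.0 ± 22.2 CPM with and 7.46 ± 1.3 without resveratrol in wild-type pools, against 18.3 ± 1.21 and 32.9 ± 0.781 under the knockout label (log2 −3.14). C1qb measured 18.6 ± 18 and 0.684 ± 0.681, against 10.9 ± 7.22 and 66.5 ± 6.36 (log2 −7.13, SE 1.29, adjusted p = 0.0236). Of 17 macrophage markers 5 had a more negative effect (9 adjusted over the list alone; adjusted p = 1.32e-11, and adjusted p = 0.101 with an estimated correlation). Among antioxidant genes Prdx5 did (log2 −1.11). No oxidative phosphorylation gene passed, yet 54 of 56 lay below 0, at a median of −0.56 (adjusted p = 9.84e-15, and adjusted p = 0.264 with an estimated correlation). Cholesterol synthesis had 23 of 24 below 0 (adjusted p = 2.65e-07, and adjusted p = 0.304 with an estimated correlation). Among wild-type pools the count was 16 without resveratrol replicate 3, and 8 and 4 without control replicates 1 and 2. Under the knockout label it was 14, 7 and 13 without resveratrol replicates 1, 2 and 3, and 18 and 51 without control replicates 2 and 3. It was 2 at one depth.

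Whether resveratrol moved genes against their change with age was examined by the correlation of both effects across the 17558 genes, which are not independent replicates. In wild-type pools Pearson's r was −0.103, where 100 simulations without effects gave −0.295 to −0.242 because both effects use the old controls. The covariance, −0.0758, exceeded the simulated −0.108 by 0.0318. Under the knockout label r was −0.359, within the simulated range of −0.361 to −0.314, and the covariance, −0.184, lay 0.0804 under the simulated value (difference −0.0804). With the resveratrol effect under the other label, which shares no control, r was −0.0384 for age in wild type (simulated −0.0160 to 0.0252) and 0.0772 for age under the knockout label (simulated −0.0304 to 0.0173). Of the genes called in wild-type pools, 3 rose with age and fell with resveratrol, 1 fell with age and rose with resveratrol, and 2 rose with both, where independent lists would share 0.674, 1.4 and 1.73. Under the knockout label 3, 2 and 0 did, where independent lists would share 0.123, 0.0215 and 0.0819. Those values leave out the shared old controls, so they are not what unchanged groups would give. Age under the knockout label and resveratrol in wild type share no library. There 93 genes rose with both and 11 rose with age and fell with resveratrol, where independent lists would share 8.39 and 3.28.

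In young granulosa cells, the pools labelled knockout differed from wild type in 20 genes, 18 higher and 2 lower. Without knockout-labelled replicate 2, a planned setting that leaves only the shallow young pools, 23 were higher and 24 lower. By DESeq2 80 were higher and 65 lower. The clone genes RP23-79J21.2 and RP23-79J21.3, with identical counts, rose from 2.53 ± 3.16 to 172 ± 53.6 CPM (SD, n = 3 each; log2 6.14, SE 0.48, adjusted p = 6.83e-08). The keratin gene Krt23 rose from 3.33 ± 2.38 to 94.4 ± 24.5 CPM (log2 4.70, SE 0.60, adjusted p = 0.00017) and Prdx5 from 106 ± 8.55 to 208 ± 7.69 (log2 0.97). H2-K2, annotated as a transcribed pseudogene of the histocompatibility genes and so uncertain, was at least 10.5-fold higher. Pcyox1 (log2 −1.49) and Prss35 (−1.55) fell. Of 28 antioxidant genes 1 rose (3 adjusted over the list alone; adjusted p = 0.000526), and of 56 oxidative phosphorylation genes 0 passed, with 50 above 0 (adjusted p = 3.77e-06). Both had adjusted p = 0.614 with an estimated correlation. The count was 12, 10 and 8 without wild-type replicates 1, 2 and 3, and 70, 47 and 118 without knockout-labelled replicates 1, 2 and 3. No direction here rests on Tet2, which was not lower under the knockout label.

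In old control granulosa cells 678 genes differed between labels, 497 higher and 181 lower under the knockout label, and the rises include leukocyte transcripts. Of 17 macrophage and leukocyte markers 13 rose (14 adjusted over the list alone; adjusted p = 2.58e-22, and 0.0116 with an estimated correlation), including Cd52 from 34.5 ± 4.98 to 121 ± 7.49 CPM (SD, n = 3 each; log2 1.8, SE 0.24) and Tyrobp (log2 4.51). Lyz1 rose to 35.5 ± 12.4 from 0.0700 ± 0.0743 CPM (log2 8.42, SE 0.96, adjusted p = 3.54e-05) and the complement gene C1qc to 60.7 ± 11.8 from 0.431 ± 0.296 (log2 6.94). Of 22 inflammatory genes 8 rose, also 8 adjusted over the list alone (adjusted p = 1e-05, and 0.0354 with an estimated correlation). They include the cytokine genes Il6 (5.34 ± 3.86 to 52.8 ± 14.1 CPM; log2 3.26) and Cxcl2 (log2 4.23). Macrophage markers took 0.159 ± 0.0176% of counts in these pools and 0.0198 ± 0.00169% in wild type.

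Between old labels, cholesterol synthesis genes rose in 6 of 24 (11 adjusted over the list alone), among them Stard4 (log2 1.27, SE 0.26) and Ebp (0.82), with an adjusted p of 3.82e-06 (adjusted p = 0.265 with an estimated correlation). Oxidative phosphorylation genes rose in 15 of 56 (38 up and 2 down adjusted over the list alone), such as Cycs, cytochrome c (log2 0.92), with an adjusted p of 3.18e-15 (adjusted p = 0.178 with an estimated correlation). Luteinization and steroidogenesis genes fell in 4 of 18 (7 adjusted over the list alone; adjusted p = 0.00355, and adjusted p = 0.191 with an estimated correlation). Adh1, alcohol dehydrogenase 1, fell from 168 ± 5.43 to 10.6 ± 2.29 CPM (log2 −3.98, SE 0.73, adjusted p = 0.00262). The clone genes RP24-250M7.2 (log2 −3.87), RP23-463H24.2 (−4.63) and RP23-183O12.2 (−3.88) fell as well. Without wild-type replicates 1, 2 and 3 the count was 200, 185 and 332, and without knockout-labelled replicates 1 and 2 it was 281 and 224. It was 140 at one depth and 1284 without the 5 shallow young libraries.

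Genes near Tet2 on chromosome 3 were over-represented among these calls. This test and its window of 10 Mb were chosen after the data were seen, and it treats neighbouring genes as independent. Within 10 Mb of the gene, 12 of 71 tested genes passed, or 16.9%, against 4.08% of 13475 elsewhere (Fisher's exact test, two-sided, p = 3.15e-05, adjusted over 6 comparisons 0.000189). They were Mcub, Casp6, Pla2g12a, Adh5, Tspan5, Mttp, Cisd2, H2afz, Adh7, Rpl34, Adh1 and Lamtor3, named after their values were seen. Adh1 lies at 138260991 to 138290698 and Rpl34 at 130726831 to 130730398. In young granulosa pools 0 of 71 genes near Tet2 passed between labels, against 12 of 13475 elsewhere (Fisher's exact test, two-sided, p = 1). In oocytes 3 of 73 genes near Tet2 passed for genotype, Mcub, Sgms2 and Rpl34 (Fisher's exact test, two-sided, p = 7.51e-05, adjusted 0.000225). These belong to the 29 oocyte calls, which fell to 0 without old knockout oocytes of either treatment and to 8 with strata as a block. Rpl34 was 612 to 916 CPM in old pools labelled knockout and 61.9 to 99.1 in old wild-type pools, with or without resveratrol. It has processed pseudogene copies, so its counts are uncertain. Young knockout-labelled replicate 2, at 38.4 CPM, differed from its group's 419 and 358.

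**Figure D3:**
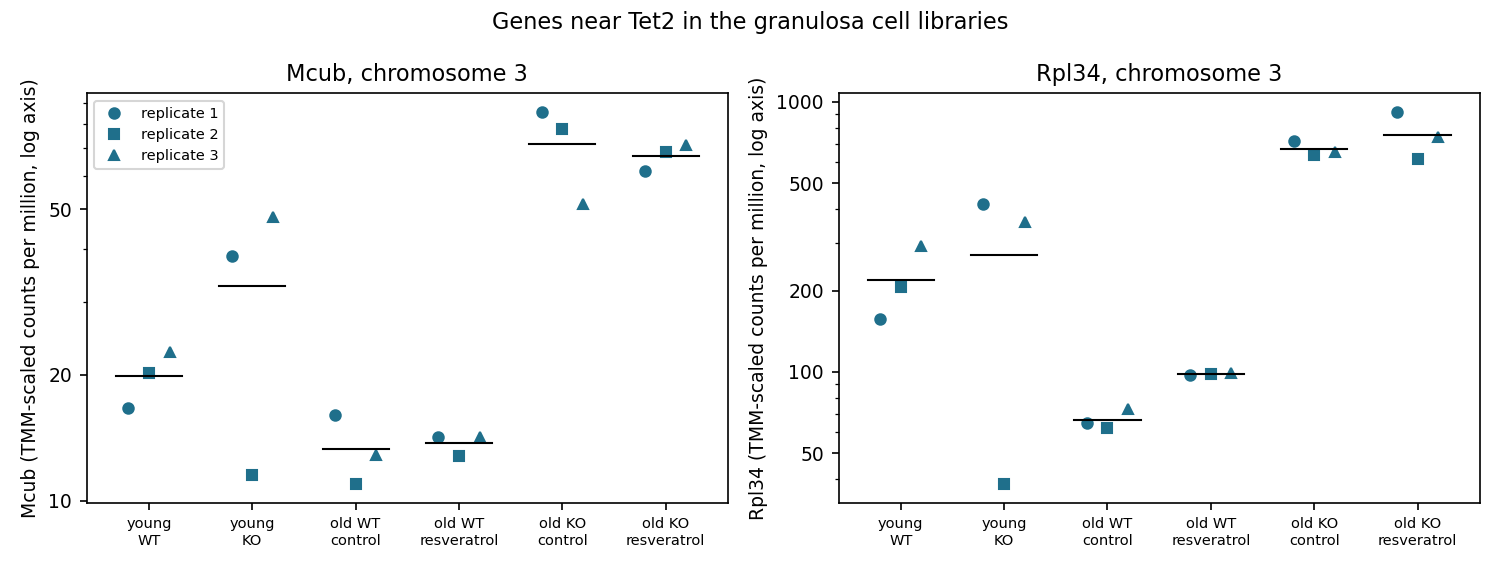
Mcub and Rpl34, neighbours of Tet2 on chromosome 3, in TMM-scaled CPM on a log axis for each granulosa library; points are libraries and lines group means. Old pools labelled knockout lie above old wild-type pools for both genes, and young knockout-labelled replicate 2, at 38.4 CPM for Rpl34, lies below the other 2 of its group.

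The age effect differed by label in 24 granulosa genes, 6 more positive and 18 more negative under the knockout label. RP24-250M7.2 had 0 counts in young and was at 65.8 ± 5.77 CPM in old wild-type pools, and at 23.9 ± 14.5 and 4.45 ± 1.00 under the knockout label. Dynlt1, a dynein light chain gene, measured 66.3 ± 9.7 and 73.1 ± 3.42 CPM in young and old wild-type pools, and 72.1 ± 13.1 and 12.7 ± 1.88 under the knockout label (log2 −2.61). Pdia4, an endoplasmic reticulum disulphide isomerase gene, had a difference of −2.87 (SE 0.55, adjusted p = 0.026). Ribosomal protein genes lay above 0 in 39 of 45 with 0 passing (adjusted p = 4.34e-06, and adjusted p = 0.605 with an estimated correlation). The count was 14 and 14 without young wild-type replicates 2 and 3, and 16 without old wild-type replicate 1. Under the knockout label it was 58 and 41 without young replicates 1 and 3. Without young replicate 2, the deep library, 11 were more positive and 12 more negative, and 14 of these were among the 24.

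**Figure D4:**
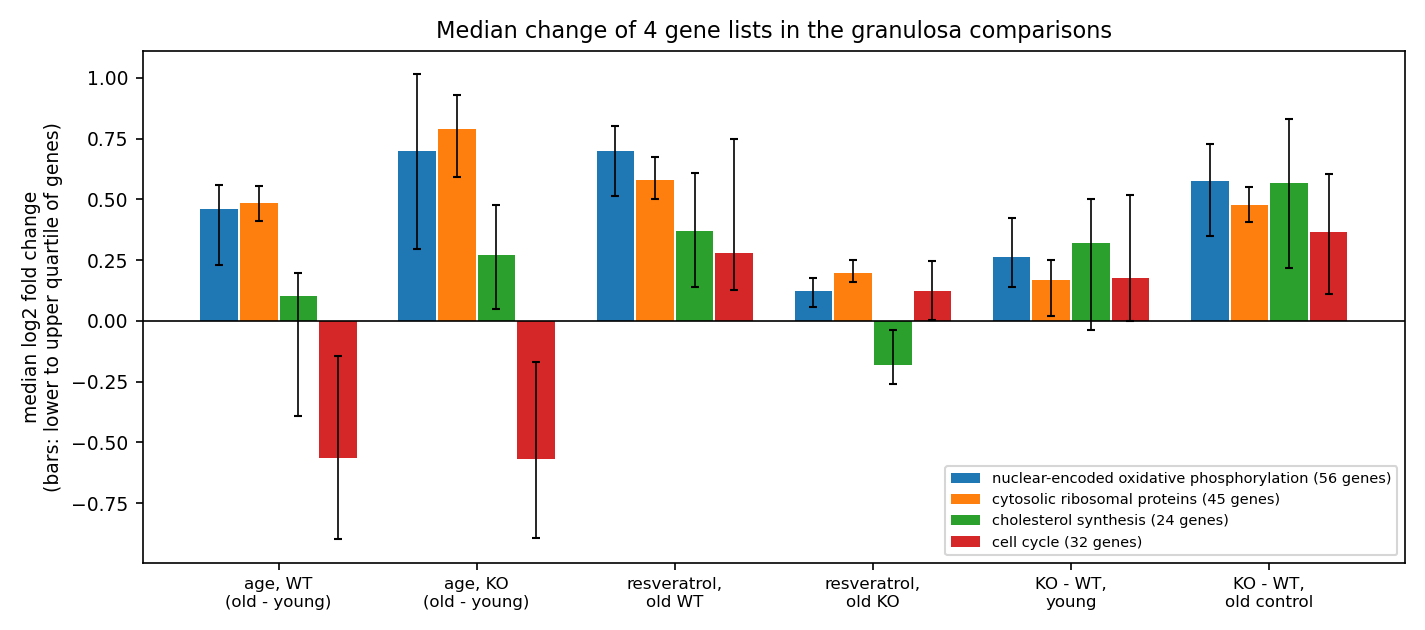
Median log2 fold change of 4 gene lists in 6 granulosa comparisons; error bars run from the lower to the upper quartile of a list's genes. The oxidative phosphorylation list has a median of 0.70 for resveratrol in old wild-type pools and 0.12 in old pools labelled knockout.

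In oocytes, age was compared over the group sums of both genotypes. Aph1c, a gamma-secretase subunit gene on chromosome 9, was lower in old than in young oocytes, at 14.0 ± 6.48 against 61.7 ± 36 CPM (log2 −2.31, SE 0.17, adjusted p = 0.0024), in 2 of 2 strata. It was the only gene past the threshold in edgeR (2809 at an unadjusted p under 0.05, 571 by DESeq2). Aph1b is a close copy, so the counts of Aph1c are uncertain. Aph1c was also lower in knockout than in wild-type oocytes (log2 −1.19, adjusted p = 0.0116). In the C57BL6 sums, which include no young oocytes, it stood at 3.17 to 5.41 CPM. There its log2 ratio of old to middle-aged controls was −0.34 (counting interval −0.63 to −0.05). Akr1c18, which encodes an enzyme that degrades progesterone, was the only gene called between old and middle-aged oocytes. It measured 13.3 and 10.6 CPM in the sums of middle-aged knockout control and resveratrol oocytes and at most 0.12 in all others. Middle-aged and young oocytes differed in 0 genes by edgeR (1905 at an unadjusted p under 0.05, 210 by DESeq2). The cumulus and granulosa marker list was lower in old than in middle-aged oocytes, with 0 of 16 passing and 5 adjusted over the list alone (adjusted p = 4.79e-06, and adjusted p = 0.652 with an estimated correlation). Heat shock genes were higher, with 0 of 18 passing and 2 adjusted over the list alone (adjusted p = 0.0161, and adjusted p = 0.652 with an estimated correlation). Ribosomal protein genes were above 0 in 39 of 45 for old against young (adjusted p = 0.0077, and adjusted p = 0.979 with an estimated correlation). The old against young count was 0 without old wild-type control oocytes, 10 (8 higher and 2 lower) without middle-aged wild-type resveratrol oocytes and 65 without young knockout oocytes. The last of these omissions gave 37 genes between middle-aged and young oocytes, and the second gave 10. Between old and middle-aged oocytes the call of Akr1c18 was lost, with 0 genes passing, without any 1 of the 4 knockout groups of these ages or old wild-type resveratrol oocytes, and the count was 4 and 6 without middle-aged and old wild-type controls (3444 at an unadjusted p under 0.05 and 814 by DESeq2 with all groups).

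Knockout oocytes differed from wild type in 29 genes, 8 higher and 21 lower, over all ages and treatments, and in 8 genes, 4 higher and 4 lower, with age and treatment strata as a block. Rpl34 rose from 6.58 ± 2.33 to 19.6 ± 3.06 CPM (SD, n = 5 sums each; log2 1.61, SE 0.23, adjusted p = 0.036), and Htatsf1 from 21.7 ± 7.57 to 38.9 ± 9.81 (log2 0.87, SE 0.13). Spopl, a ubiquitin ligase adaptor gene, fell from 105 ± 32.5 to 24.7 ± 12.6 CPM (log2 −2.11, SE 0.24, adjusted p = 0.0173). Sgms2, a sphingomyelin synthase gene near Tet2 (131318985 to 131491411), fell from 13.3 ± 5.57 to 2.99 ± 0.979 (log2 −2.10), and the interferon-induced Bst2 from 22.6 ± 3.4 to 8.90 ± 2.27 (log2 −1.37). The clone gene RP23-183O12.2 fell (log2 −3.38), as it did in old granulosa pools labelled knockout. Each of these held in 5 of 5 strata, which is no added support for genes taken by size, because the naming rule requires it of them. The largest called rises, named after their values were seen, were Akr1c18 (log2 7.06), Timp1 (6.47) and Inpp4b (3.77). Akr1c18 was also the age call given above, with its counts almost all in the middle-aged knockout sums, so its genotype call rests on that age. Of 45 ribosomal protein genes 39 lay above 0, Rpl34 passed, and 4 rose adjusted over the list alone (adjusted p = 1.07e-07, and adjusted p = 0.482 with an estimated correlation). The count was 0 without old knockout oocytes of either treatment, and 85 and 84 without young wild-type and young knockout oocytes. It was 13 and 6 without middle-aged wild-type resveratrol and control oocytes, 11 and 12 without the old ones, and 17 and 13 without middle-aged knockout resveratrol and control oocytes. Rises outnumbered falls without middle-aged wild-type resveratrol oocytes (7 and 6) and without old wild-type control oocytes (9 and 3). DESeq2 called 579.

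Resveratrol changed no gene in these oocytes past the threshold in edgeR (362 at an unadjusted p under 0.05), 0 by limma-trend and 14 by DESeq2. Leaving out any group sum gave 0 genes. Ribosomal protein genes were below 0 in 33 of 45, at a median of −0.12 (adjusted p = 0.0347, and adjusted p = 0.922 with an estimated correlation), with 0 passing. The treatment by genotype interaction called 0 genes (535 at an unadjusted p under 0.05, 20 by DESeq2), 6 without old wild-type resveratrol oocytes and 1 without old knockout resveratrol oocytes. There, 44 of 45 ribosomal protein genes were more negative under knockout (adjusted p = 8.13e-09, and adjusted p = 0.863 with an estimated correlation).

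The C57BL6 oocytes numbered 11 middle-aged controls, 6 old controls and 10 old with resveratrol, each pooled to 1 sum, so the ratios have no replicate check. Old against middle-aged controls, Rfwd2, an E3 ubiquitin ligase gene, was higher (386 against 30.8 CPM; log2 3.65, counting interval 3.57 to 3.73), as were Abhd17c (3.62), Zmynd19 (3.09) and Dnajc21 (3.04). Wtap, a subunit of the RNA methyltransferase complex, was lower (53.4 against 794 CPM; log2 −3.89, −3.96 to −3.83), as were Nptn (−3.20), Lrrc8a (−3.10) and Slc24a5 (−2.10). The median log2 ratio of all genes was −0.18, and total-count scaling moved it up by 0.11. Cholesterol synthesis had a median of −0.45, at percentile 0.14 of random lists, with 8 of 23 genes above 0. Cumulus and granulosa markers had a median of −0.65 (percentile 0.83), with 2 of 8 above 0. Macrophage and leukocyte markers had 11 of 14 above 0, at percentile 100. Their share of counts had a median of 0.00334% over old and 0.00277% over middle-aged control oocytes, and 1 old control oocyte held 0.0116%.

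With resveratrol, old C57BL6 oocytes had more Coil, which encodes the Cajal body protein coilin (57.3 against 9.46 CPM; log2 2.6, 2.45 to 2.75), Idua (1.95) and Mis18a (1.63). They had less Gli3 (log2 −1.88), Mtfr2 (−1.63) and Oog1 (−0.94). Oxidative phosphorylation genes had a median of 0.31 with 46 of 56 above 0, and ribosomal protein genes a median of 0.31 with 44 of 45 above 0. Both lay above every one of the 10000 random lists. Macrophage and leukocyte markers had 11 of 17 above 0, at percentile 98.5, and took a median of 0.00342% of counts over resveratrol oocytes, 1 of which held 0.0324%. Histone modifiers had a median of −0.21 (percentile 0.03), with 7 of 31 above 0. Tet1 was 0.10 for age (counting interval −0.23 to 0.44) and 0.43 for resveratrol (0.14 to 0.72), Tet2 −0.01 and 0.15, and Tet3 −0.04 and −0.40.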

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

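All tests in this part were chosen after the results they bear on were seen, except the test of oocyte carry-over and the splits of the samples other than those within strata.

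Young and old wild-type granulosa pools differed in 268 genes, with oocyte transcripts among the falls. Oocytes carried into the young pools are a candidate source: all of 40 oocyte transcripts (100%) had a young wild-type to oocyte ratio within 4-fold of the median, 0.694% of the oocyte level, although a strainer was used to remove oocytes, and they were taken at 1000 CPM or more in young oocytes and at most 1 CPM in old pools, so that their low level in old pools follows from the choice. Gdf9 and H1foo stood at 85.2 ± 40.0 and 54.0 ± 31.0 CPM of total counts in young wild-type pools (SD, n = 3), all 14 marker genes are in another list too, and 2 reached 1 CPM in every old wild-type control pool. A batch of the 5 shallow libraries cannot be told apart from age, because every young wild-type pool was shallow, and the same sign of 76.1% of the 268 genes (61.7% of all genes) between the deep and the shallow young knockout-labelled pools rests on replicate 2, the deep one. In that library 78.7% of the 268 genes lay nearer the old than the young wild-type mean, against 43.7% and 42.2% in replicates 1 and 3, so a wrong age label on it, which would make that contrast one of old against young, stays open, and a biological change with age stays untested.

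Leukocyte transcripts set old control pools labelled knockout apart, within a difference of 678 genes. Leukocytes in the pools are a candidate source: 76.5% of the 17 markers were called higher and none lower, Lyz2 stood at 863 ± 166 against 21.2 ± 28.1 CPM and Cd74 at 157 ± 36.7 against 37.6 ± 10.0 (SD, n = 3). No marker is in another list, 10 reached 1 CPM in every old wild-type control, and no sort against leukocytes is named in the labels. Whether inflammatory transcripts come with these cells stays open: 87.5% of the 8 called higher (all but Ccl2, at 0.78) had a log2 change below 0 with resveratrol, as did 66.6% of all 497 genes called higher, but both comparisons use the same old controls, which gives values below 0 without an effect. More leukocytes in the ovary or more carried over at puncture were not separated, and an effect of genotype stays untested.

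Genotype calls clustered around Tet2 in old pools and in oocytes. A strain variant linked to the locus, carried with the knockout allele on a mixed C57BL6 and 129 background, is a candidate explanation: the share called near Tet2 was 4.14 times that elsewhere in old pools. Of the 12 genes called there in old controls, 10 also separated the resveratrol pools by label in the same direction, as did 38.0% of the other 666 genes called, where chance gives 5% for unchanged genes, and in young knockout-labelled replicate 2 all 10 (100%) lay nearer the old wild-type mean. A wrong genotype label on that library may account for this, but young wild-type pools themselves were nearer in 8, 6 and 5 of 10 and knockout-labelled replicates 1 and 3 in 2 and 5, and a wrong age label beside it stays open, with Adh1 at 183 CPM, against 164 to 174 in old wild-type controls and 0 to 24.3 in young wild-type pools. Its macrophage share, 0.0911% (95% Wilson interval 0.0893 to 0.0928), was above that of every wild-type pool, and its oocyte marker share, 0.00189% (0.00165 to 0.00216), was within the range of old pools, and an effect of Tet2 loss on its neighbours stays untested.

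The resveratrol effect differed by genotype label in 28 granulosa genes, and 2 of 100 splits reached that count, the real one included. The highest other split gave 73. It kept wild-type resveratrol and control pools apart with their names exchanged, so it holds the resveratrol effect in wild type. Most other splits mix resveratrol and control pools within both labels, so any resveratrol effect enters them as spread within groups. The splits therefore cannot decide whether chance gave the 28 genes. Leaving out single libraries gave 4 to 51 genes. The age effect differed by label in 24 genes, and 6 of 100 splits gave as many, the real one included. The highest other split gave 263, several times the real count. It kept young and old control pools labelled knockout apart, so it holds the age effect under that label. Most of the others that reached the count also kept young and old pools of a label apart. Splits that mix young and old pools within both labels take any age effect as spread within groups. The splits therefore cannot decide whether chance gave the 24 genes.

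Splits of 3 granulosa libraries against 3 number 10, too few to judge any of these counts. The real count and the highest of the other splits were 268 and 0 for age in wild type, 908 and 935 for age under the knockout label, 285 and 4 for resveratrol in wild type, 5 and 7 for resveratrol under the knockout label, 20 and 23 for the label in young pools, and 678 and 3 for the label in old pools. In that order 1, 2, 1, 2, 2 and 1 splits reached the real count, itself included. The split that gave 935 set young knockout-labelled replicates 1 and 3 and old control replicate 3 against the rest, which points to a structure of the samples. In oocytes 3 of 100 splits reached the 29 genes of the knockout effect, the real one included (highest other 41). The other splits mix genotypes as well as ages and treatments. Any genotype effect enters them as spread, so they cannot exclude chance. Splits that exchange genotypes within strata of age and treatment number 16, too few to judge the count, and 2 of them reached it, the real one included (highest other 35). The count was 8 with strata as a block and 0 without old knockout oocytes of either treatment. For old against middle-aged oocytes 7 of 34 splits reached the 1 gene (highest other 11), and for resveratrol the real count is 0, which all 100 of 100 splits reach by construction, so they decide nothing. There the highest other was 245 genes, in a split of middle-aged wild-type control, young knockout and both middle-aged knockout groups against the rest, which points to a structure of the samples.

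In the C57BL6 oocytes 5 single values lay far from the rest of their group, out of 20 measures of groups tested, where chance gives about 1 in 20. Only the old C57BL6 control and resveratrol groups were of a size that this check covers, so such values may not be particular to them. Among middle-aged knockout control oocytes, which were not checked, the highest macrophage share was 0.0388% (median 0.00304%). An old control oocyte had a macrophage marker share of 0.0116% (group median 0.00334%, n = 6). Old resveratrol oocytes held 1 library of 10.97 (median 5.89, n = 10) in total counts, in units of 1000000. In the same group the highest macrophage share was 0.0324% (median 0.00342%), the highest Tet1 level 11.1 CPM (median 4.97), and the lowest Tet3 level 275 CPM (median 397).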

How the results depend on the processing

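The settings with thinned libraries, without shallow libraries, with only shallow young pools, with sums per header number and with the unassigned C57BL6 library were chosen after the data were seen; the rest were planned. Depth limits the granulosa comparisons: thinning lowered the count from 285 to 8 for resveratrol in wild type, 678 to 140 for the label in old pools, 28 to 2 for the resveratrol interaction, and 268 to 173 and 908 to 341 for age, and gave 22 against 20 for the label in young pools and 23 against 24 for the age interaction. Among named genes 2110 of 2708 values kept their direction and side of the threshold, and 541 lost significance. Another 57 changed direction, all in genes not called by the main test, and 0 values of called genes reversed. Among gene lists 540 of 620 kept both and 77 lost significance, while 3 that had not passed changed direction. For C57BL6 genes 21 of 40 values were counted as unchanged and 19 as moved. The cause of a change was not tested except where fewer genes, samples or counts entered. The majority direction turned in several settings. For age in wild-type granulosa cells, 148 higher and 120 lower became 82 and 137 with RLE size factors, 197 and 326 with DESeq2, 397 and 539 with only the groups compared, 130 and 141 with a stricter filter, and 53 and 58 without young replicate 2. For resveratrol in wild type, 205 and 80 became 260 and 282 without a filter, and under the knockout label 2 and 3 became 5 and 1 without resveratrol replicate 1, 11 and 8 without control replicate 3, 2 and 1 with a stricter filter, and 1 and 1 without resveratrol replicate 3. For the label in young pools, 18 and 2 became 23 and 24 with only shallow young pools. That setting is the same fit as the planned one without young knockout-labelled replicate 2. For knockout oocytes, 8 and 21 became 7 and 6 without middle-aged wild-type resveratrol oocytes, 9 and 3 without old wild-type control oocytes, and 4 and 4 with strata as a block. For old against young oocytes, 0 and 1 became 8 and 2 without middle-aged wild-type resveratrol oocytes, and for old against middle-aged oocytes 1445 and 1436 with sums per header number.

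With DESeq2 the counts were 523 for age in wild-type granulosa cells, 914 and 16 for resveratrol in wild type and under the knockout label, 145 and 1041 for the label in young and old pools, 74 and 90 for the resveratrol and age interactions. In oocytes it called 571 (old against young), 210 (middle-aged against young), 814 (old against middle-aged), 579 (knockout), 14 (resveratrol) and 20 (interaction). Without a filter on low counts they were 785 (age, wild type), 542 and 132 (resveratrol), 215 (label, young), 252 and 129 (interactions), and in oocytes 71, 7 and 199 (age) and 231 (knockout). With a stricter filter they were 176 and 3 for resveratrol, 4 for old against middle-aged oocytes and 44 for knockout oocytes.

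With only the groups compared in the model, 936 and 104 genes passed for age in wild type and under the knockout label, 1783 and 13 for resveratrol, 9 and 1134 for the label in young and old pools, and 67 for the resveratrol interaction. Thinning was to 470647 counts each, and gave 0 genes for resveratrol under the knockout label. The 0 is from edgeR, which called 618 genes at an unadjusted p under 0.05 at full depth. Without the 5 shallow libraries there were 960 and 12 for resveratrol, 1284 for the label in old pools and 71 for the resveratrol interaction, and with only shallow young pools 47 for the label in young pools. RLE size factors gave 165 for resveratrol in wild type.

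Summed per group and header number, oocytes gave 2210, 574 and 2881 genes for age and 1474 for knockout. These sums may share mice, so the counts are too high if they do. The comparison of old and middle-aged oocytes gave 0 with limma-trend (3444 at an unadjusted p under 0.05 in edgeR), and knockout gave 8 with strata as a block. With an estimated inter-gene correlation 3 of 79 list calls passed.

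The replicate numbers did not pair the granulosa libraries. Over 45 same-numbered pairs the median correlation of deviations from the group means was −0.0123 (−0.163 to 0.150), 1 was over 0.1, and 5 of 18 libraries correlated best with their own number. With the number as a replicate block 107 genes passed for resveratrol in wild type, and no other count moved by over 1.5 times.

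Leaving out 1 library at a time gave 60 to 120 genes for age in wild type, 343 to 1397 for age under the knockout label, 3 to 80 and 0 to 19 for resveratrol, 8 to 118 and 185 to 954 for the label in young and old pools, 4 to 51 for the resveratrol and 14 to 58 for the age interaction. Leaving out 1 oocyte sum gave 0 to 65 (old against young), 0 to 37 (middle-aged against young), 0 to 6 (old against middle-aged), 0 to 85 (knockout), 0 to 0 (resveratrol) and 0 to 6 (interaction).

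The correlation of age and resveratrol effects across genes was −0.103 in wild type and 0.0734 over the genes above the median expression, where simulations without effects gave −0.295 to −0.242 and a mean of −0.368, because both effects use the old controls. Under the knockout label it was −0.359, and −0.329 over those genes (simulated mean −0.427). With the resveratrol effect under the other label, which shares no library, it was −0.0384 and −0.0742 (simulated mean 0.00363) for age in wild type, and 0.0772 and 0.274 (simulated mean 0.00183) for age under the knockout label.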

Other observations

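The counts and lists in this part come from planned tests, and the genes singled out were chosen after their values were seen.

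Ovulation and cumulus expansion genes were higher in old granulosa pools labelled knockout than in old wild-type pools: 4 of 17 rose, and 8 adjusted over the list alone (adjusted p = 2.87e-05, and adjusted p = 0.178 with an estimated correlation). With age under the knockout label 3 of 17 rose, and 8 adjusted over the list alone (adjusted p = 0.00274, and adjusted p = 0.248 with an estimated correlation). Old control pools labelled knockout also held a larger share of macrophage and leukocyte markers than old wild-type controls (0.159% against 0.0198% of counts). Whether the ovulation genes move with these markers was not tested. DNA double-strand break repair genes were lower with age under that label, with 0 of 24 passing and 19 below 0 (adjusted p = 0.00104, and adjusted p = 0.0684 with an estimated correlation). Erythrocyte genes were higher with age in wild-type granulosa pools, with 0 of 5 passing and 5 adjusted over the list alone (adjusted p = 1.39e-05, and adjusted p = 0.191 with an estimated correlation). In oocytes, senescence and p53 target genes were lower in knockout, with 0 of 16 passing and 14 below 0 (adjusted p = 0.00409, and adjusted p = 0.431 with an estimated correlation).

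Akr1c18, Fst, Ptx3 and Timp1 measured 13.3, 8.04, 8.68 and 17.1 CPM in middle-aged knockout control oocytes and 10.6, 1.06, 0.222 and 8.46 with resveratrol. Hyaluronidase had been used to remove cumulus cells. The share of cumulus and granulosa markers had group medians from 0.122% (young knockout) to 0.203% (middle-aged knockout resveratrol) over single oocytes, with 0.184% in middle-aged knockout controls and 0.173% and 0.178% in middle-aged wild-type control and resveratrol oocytes. Mcub, a neighbour of Tet2, was lower in knockout oocytes (log2 −1.62) and higher in old granulosa pools labelled knockout, at 51.3 to 85.4 CPM against 10.9 to 16.

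Effects in the C57BL6 oocytes were set beside those of the first oocyte table, which was made separately. Across genes, which are not independent replicates, the old against middle-aged ratios had r = 0.248 with 57.1% of genes of the same sign, and the resveratrol effects had r = 0.0861 with 53.5%. The mismatched pairs were computed too, 4 relations in all: the C57BL6 age ratios had r = 0.143 with 61.6% of the same sign against the oocyte resveratrol effect, and the C57BL6 resveratrol ratios r = −0.0544 with 48.2% against the oocyte age effect. The C57BL6 oocyte with contradictory treatment labels held 5646368 counts over 18288 genes, with Tet2 at 1.59 CPM and macrophage markers at 0.00315% of counts.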
